A study of Arabidopsis thaliana with 24 samples.

How the data were processed

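Leaves of 21-day-old Arabidopsis thaliana Col-0 plants from MS medium and short days were cut over a length of 4 mm, per the labels' protocols. The wound was covered with a film of bacterial cellulose of 1.6 mm diameter or left uncovered, and tissue within 1 mm of it was harvested 0, 3, 6 or 24 hours post-wounding (hpw). The labels list 24 samples in 8 groups of 3 biological replicates, each from 5 to 6 leaf pieces, sequenced as single-end reads of 100 bp on an Illumina HiSeq2000. The authors' processing used TopHat2, HTSeq, Cufflinks and Cuffdiff with the TAIR10 genome, per the submitters' processing notes, which give no versions and do not say what each tool did.

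The values analysed are FPKM (by name, fragments per kilobase of transcript, scaled to the number of mapped fragments) that the authors deposited as 1 value per treatment and time, so that the 3 replicates of a group stand behind a single number. How libraries and columns were scaled to each other is not stated. Per the file headers, values are given per merged locus, and a locus can hold several annotated genes. The deposited table holds 7058 loci with 7586 genes that the authors list as significantly different; the criterion and the comparison behind that selection are not given in the sources used here. Neither counts per library nor sequencing depths were part of the table, so depth is unknown and no interval for variation between replicates or for counting error, and no detection floor, could be given. Intervals in the further observations come from resampling loci, or for a share of loci from the exact binomial method, and cover the spread over loci only. A fit across the 24 libraries with limma and tests of gene sets had been planned and were not possible without values per replicate. The comparison by size described next was the planned fallback for a table of group values without significance values.

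For each comparison the log2 ratio of FPKM plus a pseudocount of 1 was taken for loci with an FPKM of at least 1 in at least 1 of the compared groups, and a locus was counted when its log2 ratio was at least 1 in size. The comparisons were covered against uncovered wounds at each time and for the mean of 3, 6 and 24 hpw, each later time against 0 hpw within each treatment, and the film by time interaction as the difference between the film ratio at a later time and that at 0 hpw. No batch is given in the labels, and at 3 and 6 hpw time after wounding also means a different time of day from that of the cut. Ratios with an FPKM listed as 0 were left out, because a listed 0 can be a failed estimate: RBCS1A, one of the most abundant leaf transcripts, is listed at 0 in both 0 hpw columns and at 9997 FPKM or more in every other column. A 0 occurs in 400 loci, and in both 0 hpw columns in 188. Of the loci, 484 hold several listed genes and 6574 hold 1, and a locus shared with a gene outside a list was left out of that list. Both of these rules were chosen after the table had been seen.

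Gene IDs were matched to the RefSeq annotation of TAIR10.1 for symbols and products. Of the 7586 IDs, 7532 matched a locus tag, and 1 entry was not given as a locus. Coordinates are those of the deposited table in TAIR10, converted to count from 1, and 83.9% of 6527 single-gene loci had the same start and end as the reference annotation. The 18 gene lists with 293 genes, of which 183 are in the table, the threshold, the comparisons, the alternative settings tried first and the rule for named genes were written before the data were examined. A list is summarised by the median log2 ratio of its loci and by that median's percentile among 10000 random lists of the same size drawn from listed loci within 10 bins of mean expression. The percentile is a description only. Coverage was uneven, with 4 of 15 auxin, 7 of 14 cytokinin response, 6 of 17 cell cycle and 7 of 21 wound regeneration genes in the table. Of the jasmonate list it held 23 of 25. Medians and counts describe the listed members and not the whole list. The 15 gene families and 3 further test lists were chosen after the data had been seen. Close copies, such as RBCS, LHCB1, GSTF6 and GSTF7, KIN1 and KIN2, or the defensins PDF1.2 and PDF1.3, share reads, and their separate values are uncertain. Loci that merge unrelated or non-coding genes had erratic values and are not interpreted; the locus of AT3G02045 and SNRNP25, for example, is listed at 1131 FPKM in uncovered and 4.34 FPKM in covered wounds at 0 hpw.

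Named genes were, for each film comparison, the 8 loci with the largest ratio in each direction, for each time comparison the 5 largest in each direction, and in both cases up to 4 members per list by size of ratio. WRKY8, MYB15, the type-A ARR genes and the CKX genes in the table were followed at every time. Members named beyond this rule, so that every list count of 5 or fewer could be read, were chosen after their values had been seen, and so were all family members. These were TAT3, RBOHD, CRF6, RD29A, IPT3, COR47, ACS6, PDF1.2A and ACS2 at 6 hpw, and others past the threshold in the same list.

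The calculation was tested on simulated data built on the 24 hpw comparison of 7058 loci: 99% of loci changed by a factor of 4 and 43% of loci changed by a factor of 2 passed the threshold, against 2.03% of unchanged loci. Changes were placed only in loci of at least 5 FPKM. The noise was 1 spread for every locus, taken from the film ratios at 0 hpw, without separate replicate or counting noise. These shares follow from that setting and are not error rates for the data, where 4.61% of loci passed at 0 hpw. Alternatives planned in advance were pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5 FPKM, and rescaling each column by the median of its ratios to the geometric mean. Alternatives added after seeing the data were the use of loci holding 1 gene only, of ratios with a listed 0, of protein-coding genes only, and of the mean of both 0 hpw values as a common baseline. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.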

Results

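Transcript levels were measured in leaves of Arabidopsis thaliana Col-0 that had been cut and then either covered with a film of bacterial cellulose or left uncovered. Bacterial cellulose is a sheet of cellulose fibrils secreted by bacteria. Each wound was 4 mm long, and a margin of 1 mm around it was sampled 0, 3, 6 or 24 hours post-wounding (hpw). The 24 libraries formed 8 groups of 3 biological replicates, and each replicate pooled 5 to 6 leaf pieces. The values compared below are 1 FPKM per group for 7058 loci, which held the 7586 genes that the authors list as significantly different. The list therefore describes genes that differed somewhere in the design and not the whole transcriptome. The table holds no value per replicate, so there is no SD, no test and no p-value for any difference below, and the sequencing depth per library is unknown. The median FPKM over listed loci ranged from 16.3 in covered wounds at 0 hpw to 22.0 in covered wounds at 24 hpw. Across loci, which are not independent replicates, the covered and uncovered values correlated with a Pearson coefficient of 0.981 at 0 hpw, 0.945 at 3 hpw, 0.895 at 6 hpw and 0.814 at 24 hpw.

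The comparison at 0 hpw asked how far covered and uncovered wounds already differed at the start of the time course. Transcripts of early jasmonate and wound signalling were lower in the covered samples. JAZ10, JAZ7 and JAZ1 encode repressors of jasmonate signalling that jasmonate itself induces. JAZ10 (AT5G13220, chromosome 5, 4218551 to 4221077 in TAIR10) stood at 14.3 FPKM in uncovered and 1.32 FPKM in covered wounds, JAZ7 at 83.3 and 12.9 FPKM, and JAZ1 (AT1G19180, chromosome 1, 6621777 to 6623668) at 191 and 39.6 FPKM. Of the 20 jasmonate loci with a ratio, 14 were lower in covered wounds by at least 1 on the log2 scale. Their median log2 ratio was -1.52, and the single member past the threshold in the other direction was TAT3 at 1.26. The wound-responsive WRKY factors WRKY40 (85.6 against 15.9 FPKM) and WRKY18 (29.5 against 5.59 FPKM) were also lower, as were WRKY33, WRKY22 and RBOHD, the oxidase of the defense oxidative burst. These made up the 5 lower loci among 12 of the pattern-triggered defense list, whose median was -0.68. In the ethylene list ORA59, ERF6 and ERF2 were lower, with a list median of -0.77, and in the reactive oxygen list the zinc-finger factors ZAT10 and ZAT12 were lower, with a list median of -0.16. The cell wall enzyme XTH22 was lower at -1.21, while the cellulose and suberin list had a median of 0.18.

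In the opposite direction at 0 hpw, the morning clock genes CCA1 (5.11 FPKM uncovered, 20.1 FPKM covered) and PRR9 (4.08 and 11.8 FPKM) were higher in covered wounds. The clock list as a whole had a median log2 ratio of -0.15. HAI1, RD20, KIN1 and RD29A of the abscisic acid list were higher and CYP707A3 lower, with a list median of 0.43. The cytokinin response regulators ARR4 (62.7 FPKM uncovered, 132 FPKM covered) and ARR7 (5.42 and 12.7 FPKM) were higher. ARR9, ARR8 and ARR5 stayed within the threshold at 0.72, 0.24 and 0.07, as did the cytokinin oxidase genes CKX4 at -0.58 and CKX7 at 0.21. WRKY8 and MYB15 were under 1 FPKM in both 0 hpw columns and have no ratio. The galactinol synthase GOLS3 was higher at 31.3 FPKM against 6.16 FPKM. Of 6349 loci compared, 293 passed a log2 ratio of 1 in size, 48 of them higher and 245 lower in covered wounds; with a pseudocount of 5 these were 152, 18 and 134. The other list medians at 0 hpw were small: 0.24 for cytokinin response, -0.32 for cytokinin metabolism and perception, 0.10 for auxin response, -0.12 for salicylate, 0.05 for wound regeneration, 0.14 for the cell cycle, 0.00 for photosynthesis, 0.02 for low oxygen, 0.41 for epidermis and guard cell and 0.20 for vasculature. With columns rescaled by their median ratios, the salicylate and photosynthesis medians took the other sign, at 0.033 and 0.095. The last 2 lists and those for auxin, wound regeneration, the cell cycle, low oxygen and cellulose and suberin rest on 5 loci or fewer at 0 hpw.

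At 3 hpw the film comparison asked which transcripts responded to the covering early. Components of pattern-triggered defense, the response to microbial molecules and damage signals, were higher under the film. WRKY29 stood at 9.75 FPKM in uncovered and 84.9 FPKM in covered wounds, WRKY22 at 7.10 and 55.7 FPKM, and FRK1, a receptor kinase gene widely used as a marker of flagellin response, at 0.985 and 8.56 FPKM. MYB15, a factor that activates lignin genes in defense, stood at 24.1 and 73.7 FPKM, whereas WRKY8 differed little, at 29.1 and 33.8 FPKM. In this list 11 of 20 loci were higher and none lower, with a median log2 ratio of 1.21. The peroxidase PER62 (AT5G39580, chromosome 5, 15847065 to 15849141) was among the 8 largest positive ratios, at 1.59 against 29.1 FPKM, and the phloem lectin PP2A5 stood at 31.9 against 400.0 FPKM. PRX71, PER4, GSTF7 and GSTU24 accounted for the 4 higher members of the reactive oxygen list, whose median was 0.71. The glycosyltransferases UGT85A1, UGT73C5 and UGT73C1, which can conjugate cytokinins, were higher by 1.89, 1.77 and 1.72, and the cytokinin oxidase CKX4 by 1.13, while CKX7 stayed within the threshold at 0.46. The median of the cytokinin metabolism list was 0.51.

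A few genes of water-deficit responses were lower under the film at 3 hpw, 4 of the 16 loci in the abscisic acid list. P5CS1, which encodes the rate-limiting enzyme of proline synthesis, stood at 133 FPKM in uncovered and 29.3 FPKM in covered wounds, and HAI1, RD20 and PP2CA were lower at -2.35, -1.41 and -1.03. The other 12 loci stayed within the threshold, and the list median was -0.57. The lipid-transfer gene LTP3 was lower at 185 against 20.7 FPKM. The auxin-responsive genes IAA1, GH3.3 and IAA3 were lower at -1.48, -1.42 and -1.05, giving a median of -1.23 over 4 loci. The jasmonate list went both ways, with TAT3, AOC3, JAZ8 and CYP94C1 higher and VSP2, VSP1 and ST2A lower, around a median of 0.07. Loci with a log2 ratio past 1 in size numbered 827 of 6697, of which 626 were higher in covered wounds, and 422 with 341 higher at a pseudocount of 5. For the remaining lists the medians at 3 hpw were -0.49 for cytokinin response, where ARR4, ARR7, ARR8, ARR9 and ARR5 stayed within the threshold at -0.17, -0.11, -0.74, -0.49 and -0.54, 0.62 for salicylate with PR5 higher, 0.26 for ethylene with ACS7 and ACS8 higher, 0.08 for wound regeneration, -0.37 for the cell cycle, -0.43 for photosynthesis, 0.12 for low oxygen with ADH1 lower, 0.26 for cellulose and suberin with FAR5 higher, 0.40 for the clock with CCA1 higher, -0.27 for epidermis and guard cell with KAT1 lower, and -0.41 for vasculature.

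At 6 hpw the same question gave larger differences in both directions. FRK1 (AT2G19190, chromosome 2, 8324653 to 8329944) reached 85.3 FPKM in covered wounds against 0.817 FPKM in uncovered wounds, a log2 ratio of 5.57. WRKY29 stood at 111 against 3.37 FPKM, and CYP71A13, which makes a camalexin precursor, at 34.3 against 0.588 FPKM. WRKY8 stood at 83.7 against 20.2 FPKM and MYB15 at 82.3 against 20.4 FPKM. The pattern-triggered defense list again had 11 of 20 loci higher and none lower, with a median of 1.33. The peroxidase PRX71 stood at 795 against 17.1 FPKM, and the reactive oxygen list had a median of 0.92 with GSTU24 as its only lower member. The suberin genes ASFT (66.8 against 1.23 FPKM) and FAR1 (679 against 78.8 FPKM) were higher, although the cellulose and suberin list, which also holds cellulose synthases, had a median of 0.02. ERF114, a wound-induced factor linked to callus and root regeneration, was higher at 53.5 against 5.92 FPKM, and WOX5 was higher by 2.26, while the wound regeneration list had a median of 0.21.

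Cytokinin-responsive transcripts were lower under the film at 6 hpw. The type-A response regulators are induced by cytokinin and dampen its signalling. ARR4 (AT1G10470, chromosome 1, 3441988 to 3444360) stood at 74.1 FPKM in uncovered and 15.6 FPKM in covered wounds, ARR7 (AT1G19050, chromosome 1, 6577833 to 6579314) at 8.66 and 2.13 FPKM, and ARR9 at 8.57 and 2.29 FPKM. With CRF2 these were the 4 lower members of the 7 loci of the cytokinin response list, whose median was -1.05. ARR8 and ARR5 stayed within the threshold at -0.99 and -0.89, as did CKX4 at 0.17 and CKX7 at -0.12. The cytokinin receptor gene WOL stood at 10.6 against 0.844 FPKM. In its list, where UGT85A1 was higher, the median was -0.17. IAA3, IAA1 and IAA19 were lower, with an auxin list median of -1.65. P5CS1 stood at 304 against 28.5 FPKM, the ferritin gene FER1 at 409 against 29.7 FPKM and the wall enzyme gene XTH31 at 258 against 17.9 FPKM. The abscisic acid list had a median of -0.25, with 5 members lower and COR47 alone higher. Of 6772 loci, 1546 passed the threshold, 1031 of them higher, and 906 with 656 higher at a pseudocount of 5.

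In the ethylene list at 6 hpw, ACS7, PDF1.3, PR4, ORA59, PDF1.2A and ACS2 were higher and ACS6 lower, around a median of 0.81. That median was -0.23 when loci with FPKM under 5 in both groups were left out, so its direction rested on weakly expressed members. The jasmonate median was -0.13, with CYP94C1, JAZ8, AOC3 and AOC1 higher and VSP1 lower. The salicylate median was 0.09 with PR5 and CBP60G higher, the cell cycle median -0.42 with CYCD1;1 lower, and the photosynthesis median -0.23. For low oxygen the median was 0.53, with PDC1 higher and ADH1 lower. For the clock list it was 0.01, with LUX and ELF4 higher and CCA1 and PRR9 lower. Epidermis and guard cell markers had a median of -0.14 and vasculature markers 0.27.

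The film difference was largest at 24 hpw. The peroxidase gene PRX52 (AT5G05340, chromosome 5, 1578869 to 1580875) had the largest positive ratio, at 3.43 FPKM in uncovered and 885 FPKM in covered wounds, followed by the glutathione transferase gene GSTU9 at 0.713 and 215 FPKM. PRX71 (AT5G64120, chromosome 5, 25659257 to 25661007) had a smaller ratio of 3.73, at 212 and 2822 FPKM. In the reactive oxygen list 9 of 12 loci were higher and none lower, with a median log2 ratio of 3.39. GSTF6 and GSTF7 belong to this list, but they are near-identical neighbours whose reads may have been divided between them. PAD3, which completes camalexin synthesis, stood at 0.347 against 96.8 FPKM, and FRK1 at 0.259 against 124 FPKM. WRKY8 (AT5G46350, chromosome 5, 18801164 to 18804056) stood at 12.5 against 89.3 FPKM and MYB15 (AT3G23250, chromosome 3, 8309209 to 8310910) at 8.67 against 46.8 FPKM. In the pattern-triggered defense list 12 of 19 loci were higher, WRKY53 alone was lower, and the median was 1.35. Ethylene-responsive defense genes were higher as well: PR4 stood at 7.81 against 198 FPKM and PDF1.2A at 3.35 against 82.5 FPKM, in a list with 7 of 13 loci higher, ACS8 and ERF6 lower and a median of 2.56. Defensin copies such as PDF1.2A, PDF1.2B and PDF1.3 are similar enough in sequence that their separate values are uncertain.

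Further genes higher under the film at 24 hpw included AZI1, a gene of systemic defense priming, at 16.7 against 1685 FPKM, the phosphate transporter PHT1-4 at 3.00 against 382 FPKM, and NIT2 at 0.393 against 125 FPKM. Fermentation and hypoxia genes were higher, with PDC1 at 0.0887 against 45.5 FPKM and HB1 at 1.62 against 31.2 FPKM. Together with ADH1 and PDC2 these were the 4 higher members among 5 low oxygen loci, with a median of 2.05. The senescence list had too few listed loci for a median; SAG13, one of them, stood at 18.2 against 471 FPKM. In the salicylate list WRKY38 and PR5 were higher around a median of 0.61. In the cytokinin metabolism list UGT73C1, UGT73C5, UGT85A1 and IPT3 were higher and LOG1 and WOL lower, with a median of 0.61.

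Photosynthesis, water-deficit and cytokinin response genes were lower under the film at 24 hpw. Of 14 photosynthesis loci, 13 were lower, with a median of -1.55. LHCB4.2 stood at 1827 against 518 FPKM, LHCA1 at 4160.4 against 1205 FPKM and LHCA3 at 7743 against 2425 FPKM. Markers of other leaf cell types were also lower: the median was -1.44 for epidermis and guard cell loci, where LTP1, PDF1 and ATML1 passed the threshold, and -0.73 for vasculature loci, none of which passed it. The cold and drought genes COR15A and COR15B, which share 1 locus here, stood at 5859 against 329 FPKM, and KIN1 (AT5G15960) at 191 against 2.90 FPKM, although KIN1 and KIN2 are close copies. In the abscisic acid list 10 of 16 loci were lower, CYP707A1 alone was higher, and the median was -1.61. ARR7 stood at 32.8 against 1.72 FPKM and ARR4 at 123 against 21.1 FPKM. ARR5 and CRF2 were lower too, CRF6 was higher, and the cytokinin response median was -1.79. ARR9 lay just within the threshold and ARR8 at -0.13, and CKX4 and CKX7 were within it at 0.61 and 0.31. VSP1 and VSP2, storage proteins induced by jasmonate, stood at 140 against 13.0 FPKM and 213 against 35.7 FPKM, and the jasmonate list had 10 of 22 loci lower, TAT3 and ST2A higher and a median of -0.85. IAA3 and IAA19 were lower, with an auxin median of -1.44.

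At 24 hpw 2574 of 6841 loci passed the threshold, 1362 of them higher and 1212 lower in covered wounds. With a pseudocount of 5 these were 1771, 910 and 861. CYCD1;1 was the single lower member of the cell cycle list, whose median was -0.41. WOX5 and NAC071 were lower in the wound regeneration list, with a median of 0.04. ASFT was higher while FAR5, FAR1 and XTH22 were lower in the cellulose and suberin list, with a median of -0.82. The clock list had a median of -0.05 and no member past the threshold.

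**Figure D1:**
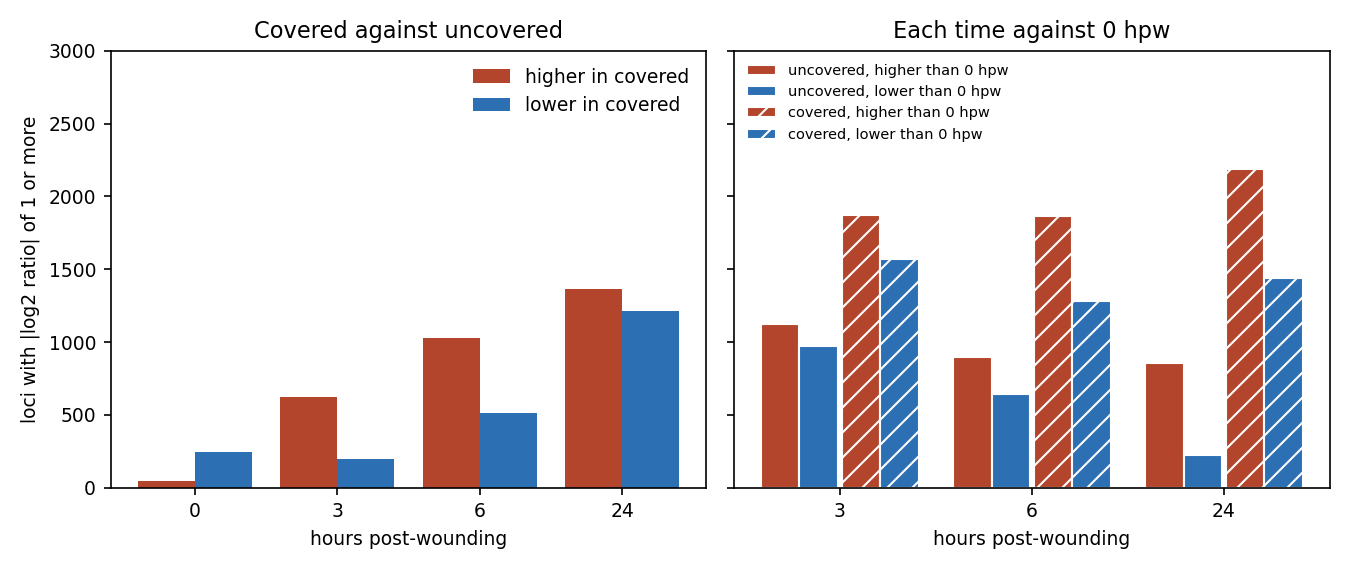
Number of loci with a log2 ratio of at least 1 in size (vertical axis) against hours post-wounding, with separate bars for loci higher and lower, on the left for covered against uncovered wounds and on the right for each time against 0 hpw within a treatment. Between covered and uncovered wounds the counts go from 48 higher and 245 lower at 0 hpw to 1362 higher and 1212 lower at 24 hpw.

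The film comparison averaged over 3, 6 and 24 hpw asked how large the difference was over the later times together, which does not require it at each of them. FRK1 had a mean log2 ratio of 4.82, WRKY29 of 4.08, PER62 of 4.62, PRX71 of 3.86, MYB15 of 1.95 and WRKY8 of 1.65. The uncharacterised gene AT1G27020 and the kinase-like gene AT3G46280 had the largest means among loci with the same sign at the 3 times, 5.09 and 5.00. LTP3 and LTP4 had the most negative means at -3.37 and -3.31, followed by AT4G23670 at -2.67 and the glutaredoxin gene GRXS10 at -2.66. ARR7, ARR4, CRF2, ARR5 and ARR9 had means of -1.79, -1.61, -1.21, -1.16 and -1.01 and ARR8 one of -0.62, so that 5 of 7 cytokinin response loci were lower and CRF6 alone higher, with a median of -1.16. CKX4 and CKX7 stayed within the threshold at 0.64 and 0.22. P5CS1 had a mean of -2.57 and IAA3 of -2.35. Of 6597 loci, 1038 had a mean past the threshold, 716 higher and 322 lower (602, 440 and 162 at a pseudocount of 5), and 243 were higher and 60 lower at all of the 3 times taken singly.

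The film ratios at different times were related across loci. Their Pearson coefficient was 0.662 between 3 and 6 hpw, 0.515 between 6 and 24 hpw and 0.440 between 3 and 24 hpw. Ratios at 0 hpw had coefficients of -0.134, 0.00280 and -0.0276 with those at 3, 6 and 24 hpw. At 6 and 24 hpw 547 loci were higher at both times, where 189 would be shared if the lists were independent, and 232 were lower at both, where 91.5 would be.

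Against 10000 random lists of listed loci matched on mean expression, the median of the pattern-triggered defense list at 3 hpw lay at percentile 100, and that of the reactive oxygen list at 24 hpw as well. The cytokinin response median lay at percentile 93.8 at 0 hpw, 1.74 at 3 hpw, 0.21 at 6 hpw and 0.01 at 24 hpw. The jasmonate median lay at percentile 0 at 0 hpw and 0.98 at 24 hpw, that of the photosynthesis list at 0.26 at 24 hpw, and that of the abscisic acid list at 100 at 0 hpw and 0 at 24 hpw. Medians of the wound regeneration list lay between percentiles 39.4 and 65.3 at the 4 times. These percentiles describe the pooled libraries and are not p-values.

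**Figure D2:**
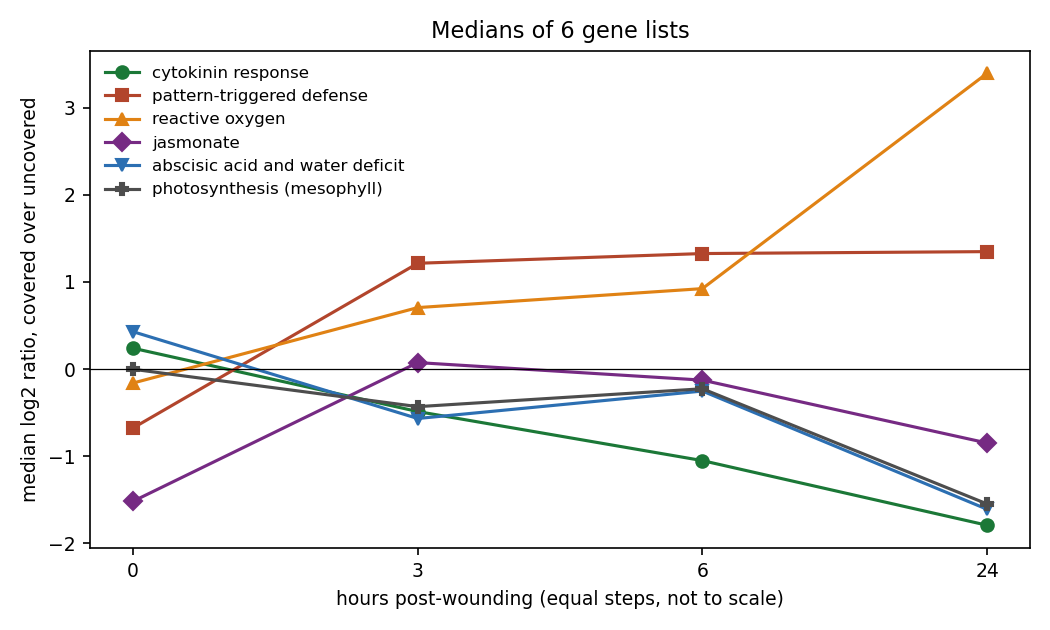
Median log2 ratio of covered against uncovered wounds for 6 of the gene lists at 0, 3, 6 and 24 hpw. Pattern-triggered defense moves from -0.68 at 0 hpw to 1.21, 1.33 and 1.35 at the later times, whereas cytokinin response moves from 0.24 to -0.49, -1.05 and -1.79. Each median covers the loci with a ratio at that time. For pattern-triggered defense these were 12 at 0 hpw and 20, 20 and 19 later, so part of its move is a change of members.

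In uncovered wounds the time course asked how transcripts differed from 0 hpw as the wound aged. The largest positive ratio at 3 hpw belonged to the wound-induced ribonuclease gene RNS1, which went from 0.457 FPKM at 0 hpw to 696 FPKM at 3 hpw and 598 FPKM at 6 hpw, and stood at 91.0 FPKM at 24 hpw. ST2A, a sulfotransferase acting on a jasmonate product, stood at 0.631, 381 and 247 FPKM at 0, 3 and 6 hpw and was back below 5 FPKM at 24 hpw. NATA1, with the largest positive ratio at 6 hpw, reached 713 FPKM from 0.438 FPKM. The jasmonate list went both ways at 3 hpw, with 8 of 21 loci higher and LOX3, LOX4, OPR3, MYC2 and JAZ7 lower, and had medians of 0.68, 1.26 and 0.95 at 3, 6 and 24 hpw. The lower ratios carry the uncovered 0 hpw values, which were above the covered ones for these genes. In covered wounds the same genes stayed within the threshold at 3 hpw against 0 hpw, at 0.63, -0.88, -0.05, -0.44 and 0.21. At 24 hpw the largest positive ratios belonged to EARLI1 (0.232 to 460 FPKM), LTP2 (2.22 to 1165 FPKM) and the glucosidase gene BGLU18 (3.27 to 1231 FPKM).

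Early in the uncovered series, salicylate and photosynthesis genes were low. WRKY70, WRKY54, PAD4 and PR5 were among the 7 of 7 salicylate loci lower at 3 hpw, and the list medians were -1.38, -0.92 and -0.48 at 3, 6 and 24 hpw. Photosynthesis medians were -1.45 at 3 hpw, with 12 of 13 loci lower, -0.83 at 6 hpw and -0.24 at 24 hpw. LLP went from 255 FPKM at 0 hpw to 1.67 FPKM at 3 hpw and 480 FPKM at 24 hpw. Ethylene medians were -1.39, -1.40 and -0.57, with ERF6 at -3.94 at 3 hpw. These also carry the 0 hpw columns, where the ethylene median for covered against uncovered wounds was -0.77. In covered wounds the ethylene medians against 0 hpw were -0.10, 0.27 and 0.48. The reactive oxygen list had medians of 1.63 at 3 hpw and 1.74 at 6 hpw and 7 of 11 loci higher at 24 hpw, the abscisic acid list had medians of 0.78, 0.39 and 0.51, and the pattern-triggered defense list of 0.37, -0.32 and 0.19. Within the last list WRKY8 and MYB15 stood well above 0 hpw, by 4.74 and 4.31 at 3 hpw, by 4.23 and 4.08 at 6 hpw and by 3.58 and 2.93 at 24 hpw.

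In uncovered wounds the cytokinin response list had medians of -0.53, -0.37 and 0.12, with ARR9 and ARR5 lower at 3 hpw, ARR5 again at 6 hpw, and ARR7 higher by 2.40 at 24 hpw. The other ratios of ARR4, ARR5, ARR7, ARR8 and ARR9 stayed within the threshold, as did CKX4 at 0.47, 0.56 and 0.46 and CKX7 at 0.25, 0.06 and -0.70. The metabolism list had medians of 0.25, 0.57 and -0.05. UGT85A1, UGT73C1, UGT73C5 and UGT76C2 were higher and LOG1 lower at both 3 and 6 hpw, so 5 of its 11 loci passed the threshold at these times, with UGT73C1 higher by 3.44 at 6 hpw. WIND1, a factor that promotes dedifferentiation at wounds, was higher by 1.62, 1.22 and 1.27, and ERF114 by 4.44, 2.75 and 3.13; with these the wound regeneration list, of which 3 loci had a ratio, had the same medians as WIND1. Further medians at 3, 6 and 24 hpw were -0.20, 0.33 and 0.82 for auxin, -0.99, -0.55 and -0.54 for the cell cycle, 1.51, 1.56 and 0.22 for low oxygen, 0.65, 0.13 and -0.37 for cellulose and suberin, 0.77, -0.08 and -0.20 for epidermis and guard cell, and -0.21, 0.02 and 0.29 for vasculature. Loci past the threshold numbered 2095 at 3 hpw (1122 higher), 1548 at 6 hpw (901 higher) and 1078 at 24 hpw (856 higher), against 1280, 890 and 584 at a pseudocount of 5. The clock list had medians of -0.80, -0.75 and -0.39, with PRR9, PRR7 and PRR5 lower at 3 hpw. At 3 and 6 hpw the time of day also differed from that of the cut, so time after wounding and clock time are not separated there. By its label 24 hpw is a full day after the cut, but collection times are not given. Morning-phased clock loci, a list chosen after seeing the data, had medians of -0.95 in uncovered and -1.57 in covered wounds at 24 hpw. For 3 evening-phased loci these were 0.66 and 0.68, so a clock difference from 0 hpw is not excluded at 24 hpw either.

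In covered wounds the same time course asked how transcripts differed from 0 hpw under the film. The extensin gene ATEXT4 (AT1G76930, chromosome 1, 28895301 to 28897120) went from 0.0671 FPKM at 0 hpw to 151, 1108 and 4201 FPKM at 3, 6 and 24 hpw. PRX71 went from 0.417 to 117, 795 and 2822 FPKM. AT4G12490, EARLI1 and AZI1 reached 5706, 3953 and 1685 FPKM at 24 hpw from less than 1 FPKM, but they lie in a cluster of similar genes, so the share of each is uncertain. At 3 hpw RNS1 (575 FPKM) and PP2A5 were among the largest positive ratios. WRKY8 was higher by 4.87, 6.15 and 6.24 and MYB15 by 5.93, 6.08 and 5.28. Pattern-triggered defense medians were 2.31, 1.17 and 1.77, reactive oxygen medians 2.28, 2.77 and 5.42, jasmonate medians 1.32, 2.17 and 1.06 and low oxygen medians 1.06, 1.57 and 3.35. Ratios to 0 hpw carry the difference between the 0 hpw columns, where the jasmonate median for covered against uncovered wounds was -1.52; at 3, 6 and 24 hpw it was 0.07, -0.13 and -0.85. ASFT was higher by 5.48 at 6 hpw. SAG13 was higher by 8.04 at 24 hpw.

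Most loci of the cytokinin response list lay below 0 hpw in covered wounds, as did photosynthesis loci. The cytokinin response medians were -1.51, -2.02 and -2.23, with 6, 6 and 5 of 7 loci lower. ARR4 was lower at -1.23, -3.00 and -2.59, ARR7 at -1.32, -2.13 and -2.34, ARR9 at -2.42, -2.72 and -2.23, ARR5 at -1.81, -1.98 and -1.74, and ARR8 at -1.51, -1.59 and -0.71. These ratios also carry the 0 hpw columns, where ARR4 stood at 132 FPKM in covered and 62.7 FPKM in uncovered wounds. ARR7 stood there at 12.7 and 5.42 FPKM. The film ratios of ARR4 and ARR7 at 3 hpw were -0.17 and -0.11, so their lower values at that time rest mostly on 0 hpw. At 0 hpw the film ratio was 0.72 for ARR9, and 0.24, 0.07 and -0.01 for ARR8, ARR5 and CRF2. The oxidase gene CKX4 was higher by 2.18, 1.31 and 1.65, while CKX7 stayed between -0.60 and 0.50. The cytokinin metabolism medians were 0.76, 0.29 and 0.40. GASA6, a gibberellin-regulated gene, went from 233 FPKM at 0 hpw to 10.8 and 4.01 FPKM at 3 and 6 hpw and stood at 38.6 FPKM at 24 hpw, and IAA14 went from 29.4 to 0.577 FPKM at 3 hpw. The cyclin gene CYCD1;1 was lower at -3.46, -3.43 and -2.94. Photosynthesis medians were -1.83, -1.08 and -1.74, with 12 of 13 loci lower at 3 hpw and again at 24 hpw. P5CS1 was lower at -3.54, -3.57 and -2.94 against 0 hpw, and abscisic acid medians were 0.21, -0.15 and -1.48.

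Other medians in covered wounds at 3, 6 and 24 hpw were -0.87, -0.69 and -0.04 for salicylate, -0.10, 0.27 and 0.48 for ethylene, -1.93, -1.61 and -0.80 for auxin, -1.42, -1.11 and -0.58 for the cell cycle, 0.57, -0.27 and -1.20 for cellulose and suberin, where CESA1, CESA3, XTH22 and FAR1 were lower and ASFT higher at 24 hpw, 0.04, -0.44 and -1.30 for epidermis and guard cell, and -0.88, 0.09 and -0.73 for vasculature. For wound regeneration, RAP2.6L and WIND1 were higher at each time, and the median was 1.46 at 6 hpw and 1.18 at 24 hpw. The clock medians were -0.27, -0.23 and -0.65, with CCA1 and PRR9 lower at every time. Loci past the threshold numbered 3442 at 3 hpw, 3144 at 6 hpw and 3627 at 24 hpw, with 1873, 1863 and 2189 of them higher. The balance of directions depended on scaling. When each column was rescaled by its median ratio, the median of all loci shifted by -0.11, -0.17 and -0.23 in covered wounds and by -0.14 in uncovered wounds at 24 hpw. The share of higher loci among those past the threshold in covered wounds then became 47.5% in place of 54.4% at 3 hpw, 48.8% in place of 59.3% at 6 hpw and 49.1% in place of 60.4% at 24 hpw. In uncovered wounds it became 51.1% in place of 53.6%, 50.3% in place of 58.2% and 64.4% in place of 79.4%.

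**Figure D3:**
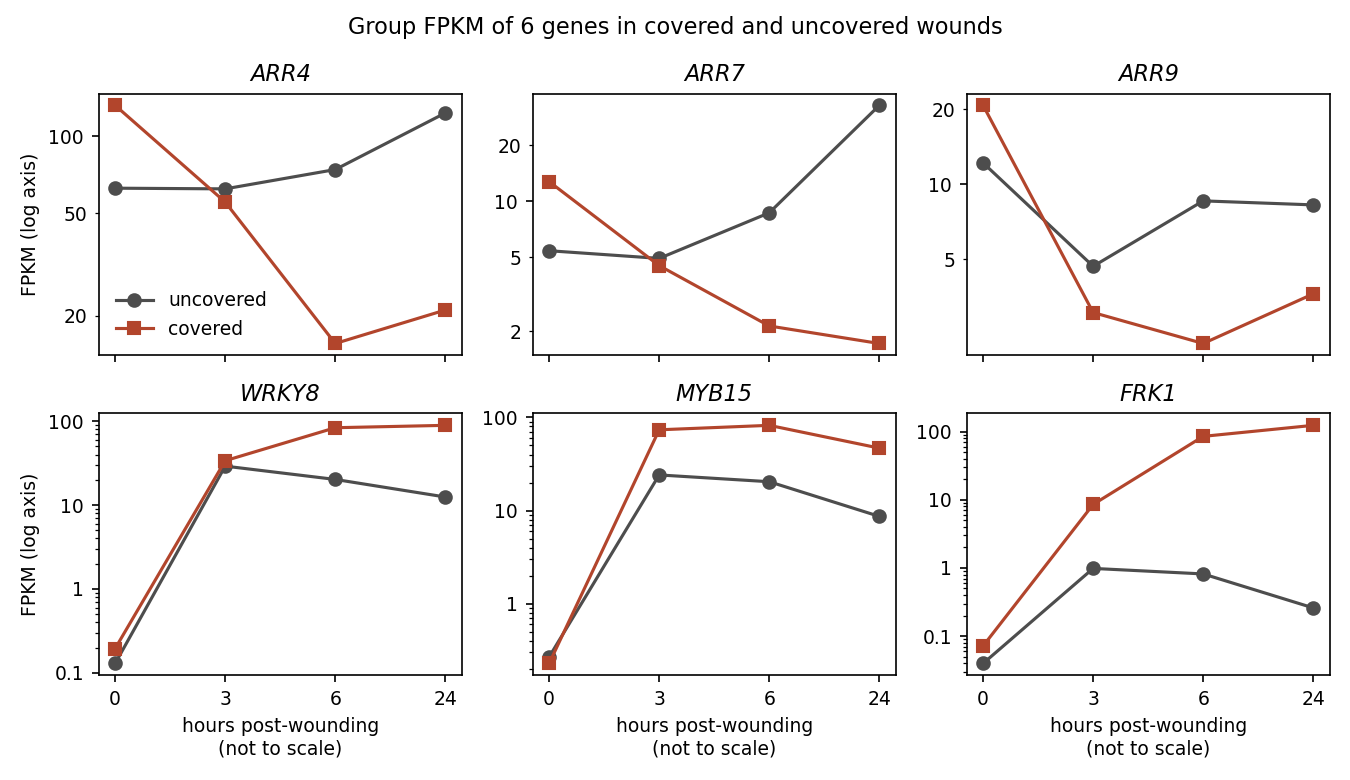
FPKM on a log axis against time after wounding for ARR4, ARR7, ARR9, WRKY8, MYB15 and FRK1 in uncovered and covered wounds, 1 value per group without error bars because the table holds no replicates. FRK1 reaches 124 FPKM under the film at 24 hpw against 0.259 FPKM without it, and ARR7 stands at 1.72 against 32.8 FPKM.

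The interaction asked whether the time courses of covered and uncovered wounds differed, as the film difference at a later time minus that at 0 hpw. It was not tested, since no replicate values were at hand. Of 6333 loci, 3313 had at least 1 of the 3 differences past 1 in size on the log2 scale, with the largest difference positive in 1842 and negative in 1471. This balance depended on scaling: with rescaled columns 1647 were positive and 1717 negative, and the median of the largest difference was -0.27 in place of 0.42. At 24 hpw 1262 loci were positive and 1164 negative, against 993 and 552 at 6 hpw and 756 and 331 at 3 hpw. ARR7 illustrates a crossing course: it was higher under the film at 0 hpw at 12.7 against 5.42 FPKM and lower at 24 hpw with a log2 ratio of -3.63. Its crossing rests on the 0 hpw columns alone, since the ratio was -0.11 at 3 hpw and -1.62 at 6 hpw. For JAZ10 the positive difference at 3 hpw rested mostly on 0 hpw, where the film ratio was -2.72, since at 3 and 6 hpw that ratio stayed within the threshold at 0.61 and -0.57.

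Loci past the threshold in the same direction at 3 hpw in both treatments stayed further from their 0 hpw level in covered wounds. Time of day also differed between 0 and 3 hpw, so these loci need not all respond to wounding. Of 882 loci higher at 3 hpw in both treatments, 43.0% were still past the threshold at 24 hpw in uncovered wounds and 71.0% in covered wounds. At 6 hpw the shares were 64.5% and 85.5%. Of 656 loci lower at 3 hpw in both, 13.4% remained lower past the threshold at 24 hpw in uncovered and 65.5% in covered wounds. GASA6 was one such locus: it stood at 202 FPKM at 0 hpw and 194 FPKM at 24 hpw in uncovered wounds, and at 233 and 38.6 FPKM in covered wounds.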

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

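Using loci with 1 gene only, ratios with a listed 0, protein-coding genes only and a common 0 hpw baseline were alternatives chosen after seeing the data; the others were planned. Counts of loci past the threshold depended most on the pseudocount. With a pseudocount of 5 they were 152 at 0 hpw, 422 at 3 hpw, 906 at 6 hpw and 602 for the mean in covered against uncovered wounds, and 1280, 890 and 584 at 3, 6 and 24 hpw in uncovered wounds, since a larger pseudocount shrinks the ratios of weakly expressed loci. The other 95 counts stayed within a factor of 1.5 of those reported. Among them, the pseudocount of 5 still lowered the film count at 24 hpw from 2574 to 1771. The counts in covered wounds at 3, 6 and 24 hpw became 2316, 2175 and 2642, and that of the interaction 2360. Without the pseudocount of 5, the film comparison ranged from 257 to 410 loci at 0 hpw, from 726 to 1077 at 3 hpw, from 1379 to 1832 at 6 hpw and from 2374 to 2893 at 24 hpw, so the order of the times was kept. Of the medians of lists and families in the film comparisons, 1236 stayed within a factor of 1.5 as ratios, not as log2 values, a tolerance within which medians near 0 can take the other sign, and 24 moved further. Among medians that stood apart from nearly all random lists, that for ethylene at 6 hpw alone reversed, to -0.23 with a minimum of 5 FPKM, because that filter removed weakly expressed members. Of the values for named genes, 187 moved further than this and 1450 did not, and none changed sign past the threshold. No paired analysis was possible because the table holds 1 pooled value per group. Leaving out replicates, a replicate block, the variance trend, fits on the compared samples only, set tests and stricter q-value thresholds were not run for the same reason, and the unknown depth leaves the precision of weakly expressed loci open.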

Other observations

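The gene families below, and the tests of column scaling, of a few loci taking the FPKM total, of the mesophyll share, of a bias against short loci and of the larger difference at 3 hpw, were chosen after the results were seen. The lists of touch and early wound loci and of morning-phased and evening-phased clock loci were also chosen after the data had been seen. The families showed which groups went with the film difference at 24 hpw. Among WRKY factors 19 of 31 loci with a ratio were higher under the film and WRKY53 alone lower, with medians of -0.40, 0.96, 0.95 and 1.40 at 0, 3, 6 and 24 hpw. Class III peroxidases had medians of -0.18, -0.34, 1.73 and 2.66, with PER12, PER42 and PER63 lower at 24 hpw. Chitinases had medians of 0.46 at 0 hpw, 1.09 at 3 hpw and 3.41 at 24 hpw, led by AT2G43590 at 16.3 against 966 FPKM, while CTL1 and CTL2, which act in cell wall formation, were lower. Glutathione transferases had a median of 0.92 at 24 hpw with GSTU20 alone lower. Of 8 loci grouped as phosphate transporters by their annotation text, 5 were higher, among them PHT1-4, MPT2 and PHF1 (6.04 against 39.0 FPKM). PHF1 is named as a facilitator of transporter traffic and not as a transporter. Proteasome subunits had a median of 0.83 at 24 hpw. Cytochrome P450 genes had a median of 0.73 at 24 hpw with 23 of 60 loci higher, among them PAD3 and CYP71A12, and 5 lower. NAC factors had a median of 0.92 with 6 of 15 higher, led by JUB1, and 1 lower. Heat shock proteins had medians of -0.52, 0.77, 0.29 and 0.88.

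Chloroplast-encoded genes had medians of -0.53, -0.09, -0.02 and -1.51 at the 4 times. All 43 lay below 0 at 0 hpw, with 1 past the threshold, and 35 passed it at 24 hpw. Expansins at 24 hpw had a median of -0.83 with 6 of 14 loci lower past the threshold and 4 above 0. Tubulins had a median of -0.75, at percentile 9.75, with TUBB3, TUBB5 and TUBB7 of 8 loci past the threshold. Aquaporins went both ways: PIP1-1 stood at 131 against 530 FPKM and TIP2-2 at 88.2 against 319 FPKM, whereas PIP2-6 stood at 378 against 94.5 FPKM and PIP1-3 at 122 against 29.5 FPKM. Lipid-transfer proteins also split, with 14 of 26 lower, among them LTP3 and LTP2, and 7 higher, among them EARLI1, AT4G12490 and AT4G12500. Ribosomal protein loci had medians of -0.61, -0.22, -0.41 and -0.19 at the 4 times. Only RPL41G and AT4G12600 of 118 passed the threshold at 0 hpw, against 2 higher and 13 lower of 120 at 24 hpw.

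Intervals given with the patterns below describe the spread over loci of pooled values and not variation between replicates, so no replicate check stands behind what they argue against. The first pattern is the lower level of jasmonate and wound genes in covered wounds at 0 hpw. A single scaling factor left between the deposited columns is argued against, because the median of all 6349 loci was -0.035 (bootstrap interval -0.045 to -0.025). How the authors scaled the columns to each other is not stated. A median near 0 may follow from that step, so it says nothing about differences between libraries before it. The ratio did go with locus length at 0 hpw, with a Spearman coefficient of 0.275 and a median of -0.25 for loci under 1000 bp against -0.03 for longer ones. This trend is argued against as the whole cause, since the jasmonate median lay -1.45 (-1.97 to -0.76) from lists matched on locus length. Ribosomal and chloroplast-encoded loci were also mostly below 0 at this time, and a library or RNA difference of another kind between the 0 hpw columns was not tested. More time or handling before freezing in the uncovered samples may account for it, and 12 other touch and early wound loci had a median of -0.88 (-1.30 to -0.57). Those loci are of the same kind as the pattern itself, so an early effect of the film could lower them as well. Their median therefore does not favour handling. A different time of day at collection may also contribute, since morning-phased minus evening-phased clock loci gave 1.15 (0.20 to 1.91), from medians of -0.01 and -1.16, though the latter rests on CCR2, COR27 and COR28 alone. These stay open, as does an early effect of the film, which was not tested.

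The second pattern is the lower level of photosynthesis genes in covered wounds at 24 hpw. A few strong loci taking the FPKM total would lower most loci, but the median of all loci was 0.038 (0.0026 to 0.073). The authors' scaling is not stated and may have set that median, so it speaks only against a shift left in the deposited values. At 24 hpw the 10 strongest listed loci held 9.47% of the listed FPKM sum in covered and 17.1% in uncovered wounds. A smaller share of mesophyll cells would raise markers of other cell types, yet 8 epidermis, guard cell and vasculature loci had a median of -0.80 (-1.92 to -0.68). This argues against a smaller mesophyll share as the whole cause. It cannot exclude a contribution, because these markers are among the genes the authors list as different and may themselves be regulated. A bias against short loci is argued against too, because the photosynthesis median lay -1.60 (-1.72 to -1.44) from lists matched on locus length, although loci under 1000 bp did have a median of -0.60. At 3 and 6 hpw the median of such short loci had the other sign, at 0.14 and 0.33. An effect of the film, which the design names, was not tested apart from these explanations and stays open.

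The third pattern concerns loci past the threshold in the same direction at 3 hpw in both treatments. They need not all respond to wounding, since time of day also differed between 0 and 3 hpw. These loci stood nearer to their 0 hpw level at 24 hpw in uncovered than in covered wounds. Different 0 hpw baselines are argued against as the whole cause of this pattern, since with a common baseline the share of higher loci still past the threshold was 1.62 times as large in covered wounds (1.51 to 1.74, 925 loci). Covered wounds also differed more at 3 hpw, with a median of 2.03 against 1.61 over the 882 higher loci. This is argued against as the whole cause too: among 245 higher loci whose ratios at 3 hpw agreed within 0.2, against the common baseline, that share was still 2.21 times as large in covered wounds (1.82 to 2.75). More unwounded tissue in the uncovered samples at 24 hpw cannot be told apart from a faster return: 8.50% (6.75 to 10.5) of 882 loci were higher in uncovered wounds by 1 or more on the log2 scale, between the bounds of under 5% and at least 10% set for and against dilution. Those bounds were set for the higher loci only. Of 653 loci lower at 3 hpw in both treatments, 2.45% were lower in uncovered wounds by 1 or more at 24 hpw. An effect of the film itself was not tested and stays open.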
